A study of Mus musculus with 2 samples.

How the data were processed

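Per the labels' protocols, adherent macrophages of the thioglycolate-elicited peritoneal exudate of male C57BL/6JJcl mice were kept with IL-10 at 100 ng/ml for 4 h or left untreated. The text given for the untreated sample repeats that of the treated sample, so the groups were taken from the sample titles. Library insert sizes were 188 bp (IL-10) and 197 bp (untreated). Per the submitters' processing notes, reads were aligned to the mm9 mouse genome with TopHat and processed with Cufflinks, both given without a version. The deposited values, per the file headers, are a count for each splice junction of the reads that the aligner placed across it, deposited without scaling. Cufflinks values and raw reads were not used here. From the deposited junction lists, the chromosome, start, end, strand, read count and aligned length on each side of a junction were used.

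Genes were named from the GENCODE M21 annotation, which is on a later genome build than mm9. A junction took a gene name where its chromosome, strand and exact intron length matched an annotated intron and at least 2 introns of the gene shared the same offset, up to 20 Mb. Of 131057 junctions in either library (88915 in both), 106609 (81.3%, with 98.0% of reads) matched 10710 genes. Of these, 105351 (95.9% of reads) matched 1 gene and 1258 matched several, 2.59% lay at offset 0, and 276 fitted several offsets. With intron lengths shuffled 5 times, a mean of 4.6 junctions and 2.2 genes matched. All coordinates given are those of the deposited mm9 lists.

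A gene's value was the sum of reads over introns that belong to that gene alone, divided by the library's sum over all such introns. The ratio of IL-10 to untreated carried an exact conditional binomial 95% interval (Clopper-Pearson). A gene was called higher or lower with at least 20 reads over both libraries, a ratio of at least 2 or at most 0.5, and an interval that excluded 1. Log2 ratios used a pseudocount of 0.5 reads, and a ratio against 0 reads used a floor of 3 reads. A total of 32 gene lists, with 812 entries and 745 genes, were compared by the median log2 ratio of members with at least 20 reads. That median was placed among 10000 random lists of the same size matched on abundance in 20 bins, and its counting range came from 2000 binomial resamples. For splicing, the share of reads of each junction at a donor or acceptor was compared at sites with at least 20 reads in each library. A junction was called with a difference of at least 20 percentage points and intervals that did not overlap. Junctions that matched no annotated intron were counted as outside the annotation.

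The lists, thresholds, alternatives and naming rule were fixed before the data were examined. Named genes were the 15 higher and 15 lower genes whose interval bound nearest to 1 lay farthest from it, up to 4 measured members of each list with the largest absolute log2 ratio, and 11 genes of the IL-10 response. The 10 junctions with the largest difference in share were named too. Of 146 genes so named 144 were measured. Other genes given by name were chosen after their values were seen. Some of the named genes are not reported here.

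Alternatives were the TMM factor of edgeR (0.989, IL-10 over untreated), the median-of-ratios size factor of DESeq2 (1) and the total of all junction reads, in place of the total of named reads (0.993). Minimum reads of 0 and 100, folds of 1.5 and 3, a 99% interval, a pseudocount of 5, the intron with the most reads alone, a majority of introns on the same side, and all junctions within the gene span were also tried. Splicing was recounted with 10 and 50 reads, 10 and 30 points, annotated junctions alone and an overhang of at least 10 bases. After the data were seen, 2 settings were added: introns shared with read-through models and 1538 genes with a lone matched junction (5 junctions matched with shuffled lengths, against 1597), and removal of the trend of the log2 ratio on transcript length and GC content by lowess (fraction 0.3).

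The procedure was tested on simulated data, in which read counts varied by counting error alone. Of 25 genes each made 2-fold, 3-fold and 4-fold higher, 52.0%, 100% and 96.0% were called, and of 25 made 1.5-fold higher 0 were called. The intervals covered the true ratio of 1 for 95.95% of the 8156 genes left unchanged. Of 200 simulated splicing differences of 40 points 79.0% were recovered, and 2.5% of 200 lists drawn at random fell outside the central 95%. After lowess, the trend left in simulated values had an SD of 0.00561. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.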

Results

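Interleukin 10 (IL-10) is a cytokine that restrains inflammatory gene expression in macrophages, and its receptor signals through the transcription factor Stat3. RNA was sequenced from mouse macrophages kept with IL-10 at 100 ng/ml for 4 h and from untreated macrophages, with 1 library per group. The comparison asks which transcripts and which splice junctions differ in abundance between these libraries. The cells were adherent macrophages of the peritoneal exudate of male C57BL/6JJcl mice, drawn into the peritoneum by thioglycolate, an irritant broth. The measured values are numbers of reads that span a splice junction. The IL-10 library held 3998954 such reads on 109870 junctions, and the untreated library held 4035991 on 110102 junctions, with a median of 7 reads per junction in each. Reads on introns of named genes numbered 3838067 (96.0%) in the IL-10 library and 3865085 (95.8%) in the untreated library. The lysosomal genes Psap, Ctsb and Ctss, the macrophage glycoprotein gene Gpnmb, the ferritin gene Fth1 and the elastase gene Mmp12 led both libraries, and the 10 most abundant genes took 21.2% and 21.5% of the reads. With 1 library per group, no difference given here has a replicate check. Ratios compare these libraries, not the conditions, and each 95% interval covers counting error only.

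Macrophage markers were abundant in both libraries, and a smaller share of the markers of other cell types was measured. Of 12 macrophage markers, 10 had at least 20 reads, and none was 2-fold different. The lysozyme gene Lyz2 had 31849 reads with IL-10 and 45047 without (ratio 0.712, 95% interval 0.702 to 0.722), and the growth factor receptor gene Csf1r had 6737 and 7892 (0.860, 0.832 to 0.888). Of the 3 introns of Lyz2, 2 lay on the same side as the sum. That sum leaves out an unnamed junction on chromosome 10 from 116715244, a start shared with Lyz2, to 116726174. It had 5174 and 4713 reads (1.11, 1.06 to 1.15). The integrin gene Itgam, with 521 and 397 reads, stood at 1.32 (1.16 to 1.51) and the Fc receptor gene Fcgr1 at 1.21 (1.05 to 1.41). Most reads of Itgam lay on introns shared with read-through models. With those introns included, Itgam had 9974 and 8595 reads (1.17, 1.136 to 1.204). Among 16 neutrophil markers, 4 were measured (Lcn2 1.37, Csf3r 1.17, Mmp8 1.05 and Mmp9 1.03), each with an interval that included 1. Fibroblast and mesothelial markers had 9 measured members, led by Col6a1 (1.58, 1.19 to 2.12), Col3a1 (1.38, 1.11 to 1.72), Pdgfra (1.37, 0.955 to 1.97) and Dcn (0.755, 0.576 to 0.988). Of the eosinophil and mast cell markers, Siglecf had a ratio of 1.80 (1.25 to 2.63) and Tpsb2 of 0.916. The B cell markers Ighm (0.815) and Cd22 (0.912), the platelet markers Pf4 (0.826) and Itgb3 (1.01) and the dendritic cell marker Itgax (1.09) were within 1.25-fold, and no T or NK cell marker reached 20 reads. Among 8 measured markers of resident peritoneal macrophages, the adhesion molecule gene Selp was higher in the IL-10 library with 29 reads against 6 (4.87-fold, 1.99 to 14.3), while Ltbp1 (0.627), F5 (1.58) and Timd4 (1.34) had intervals that included 1. The median log2 ratios of these lists lay within the central 95% of random lists, but few members were measured. Under alternatives, eosinophil and mast cell markers (1 gene) were at percentile 99.1 with at least 100 reads and at 99.4 on the intron with the most reads, and dendritic cell markers (5 genes) at 99.98 with no minimum of reads.

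The clearest difference between the libraries was Tgfbi, which encodes a secreted matrix protein induced by transforming growth factor beta. Tgfbi had 6452 reads in the IL-10 library and 1318 in the untreated library, 4.93-fold higher (95% interval 4.65 to 5.24), and all 16 of its introns with 5 or more reads lay on the same side. Among the other top 15 genes in this direction, the endothelin receptor gene Ednrb was 7.18-fold higher (4.17 to 13.3), the NAD-consuming surface enzyme gene Cd38 4.96-fold (3.20 to 7.95), the lymphocyte receptor gene Cd244a 10.47-fold (4.21 to 33.6) and the myeloid receptor gene Tarm1 7.89-fold (3.37 to 22.6). The arginine-degrading enzyme gene Arg1 was 3.47-fold higher (2.70 to 4.51), the inflammatory caspase gene Casp4 3.98-fold (2.96 to 5.41), the guanine deaminase gene Gda 3.51-fold (2.91 to 4.27), and the endocytic adaptor gene Dab2 2.90-fold (2.63 to 3.20). The zinc and iron transporter gene Slc39a14 was 6.13-fold higher (3.22 to 12.9). In the other direction, the hepatocyte growth factor gene Hgf was 2.12-fold lower (1.68 to 2.69) and the endoplasmic reticulum chaperone cofactor gene Sdf2l1 2.08-fold lower (1.67 to 2.60).

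Over all genes, 8356 had at least 20 spliced reads over both libraries together. Of these, 142 (1.70%) were at least 2-fold higher in the IL-10 library with an interval that excluded 1, and 123 (1.47%) were at least 2-fold lower. On the intron with the most reads alone, 45 of the 142 and 19 of the 123 were called. Most genes differed little: 7136 (85.4%) lay within 1.5-fold. The higher genes rested on more reads than the lower genes, since 37 higher and 10 lower genes had at least 100 reads. Among genes with 500 to 5000 reads, 11 were higher and 0 were lower, and above 5000 reads 2 were higher and 0 were lower. For 30 of the higher genes the lower bound of the ratio itself exceeded 2, and for 4 of the lower genes the upper bound lay under 0.5. The higher genes with above 5000 reads were Tgfbi and the osteopontin gene Spp1, the latter singled out after its values were seen, with 58937 and 28521 reads (2.08-fold, 2.05 to 2.11). In counts simulated from these libraries with counting error alone, 52.0% of 25 genes made 2-fold higher and 100% of 25 made 3-fold higher were called. Of 8156 unchanged genes 44 (0.539%) were called, none of them among the 5747 with 100 reads or more. Log2 ratios of the real libraries spread more widely than counting error. Their SD was 0.3455 against 0.2034 from counting at 100 to 500 reads, and 0.2531 against 0.0947 at 500 to 5000. The simulated rate is therefore not the share of false calls among the 142 and 123.

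Of the remaining genes of the top 15 in the higher direction, the neuregulin gene Nrg1 had 25 reads with IL-10 and 1 without (25.2-fold, 4.12 to 1034), Nxpe5 had 76 and 11 (6.96-fold), the fatty acid desaturase family gene Fads3 had 34 and 5 (6.85-fold), and Rab3il1, a regulator of Rab3 proteins, had 771 and 245 (3.17-fold, 2.74 to 3.67). The spliceosome gene Snrpe had 24 and 2 reads (12.1-fold, 3.00 to 105.5), and 1 of its introns had 5 or more reads. Exons joined at 3 of its 4 introns also occur in a processed pseudogene, so its value is uncertain. On the lower side, the largest folds rested on few reads: the Ras activator gene Rasgrp3 had 7 and 37 (5.25-fold lower, 2.31 to 14.0) and Taf4b had 2 and 19 (ratio 0.106, 0.0120 to 0.439). The interferon-inducible gene Ifi27l2a had 36 and 91 reads (2.51-fold lower, 1.69 to 3.80), the deglycosylating enzyme gene Engase 27 and 83 (3.05-fold lower, 1.96 to 4.90), and the checkpoint ligand gene Cd276 12 and 43 (3.56-fold lower, 1.84 to 7.41). The uncharacterised gene 3110009E18Rik had 21 and 81 reads (ratio 0.261). Zfp511 and the telomere-binding factor gene Terf1 each had 16 and 55 (0.293), and the ratios of Abhd3, Slfn8, Trim45 and Rnf138 were 0.159, 0.210, 0.168 and 0.288. Counted on the intron with the most reads alone, Nrg1, Tarm1, Slc39a14, Fads3, Hgf, Rasgrp3, Taf4b, Terf1, Abhd3, Cd276, Slfn8, Trim45 and Rnf138 kept their direction but were no longer called.

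**Figure D1:**
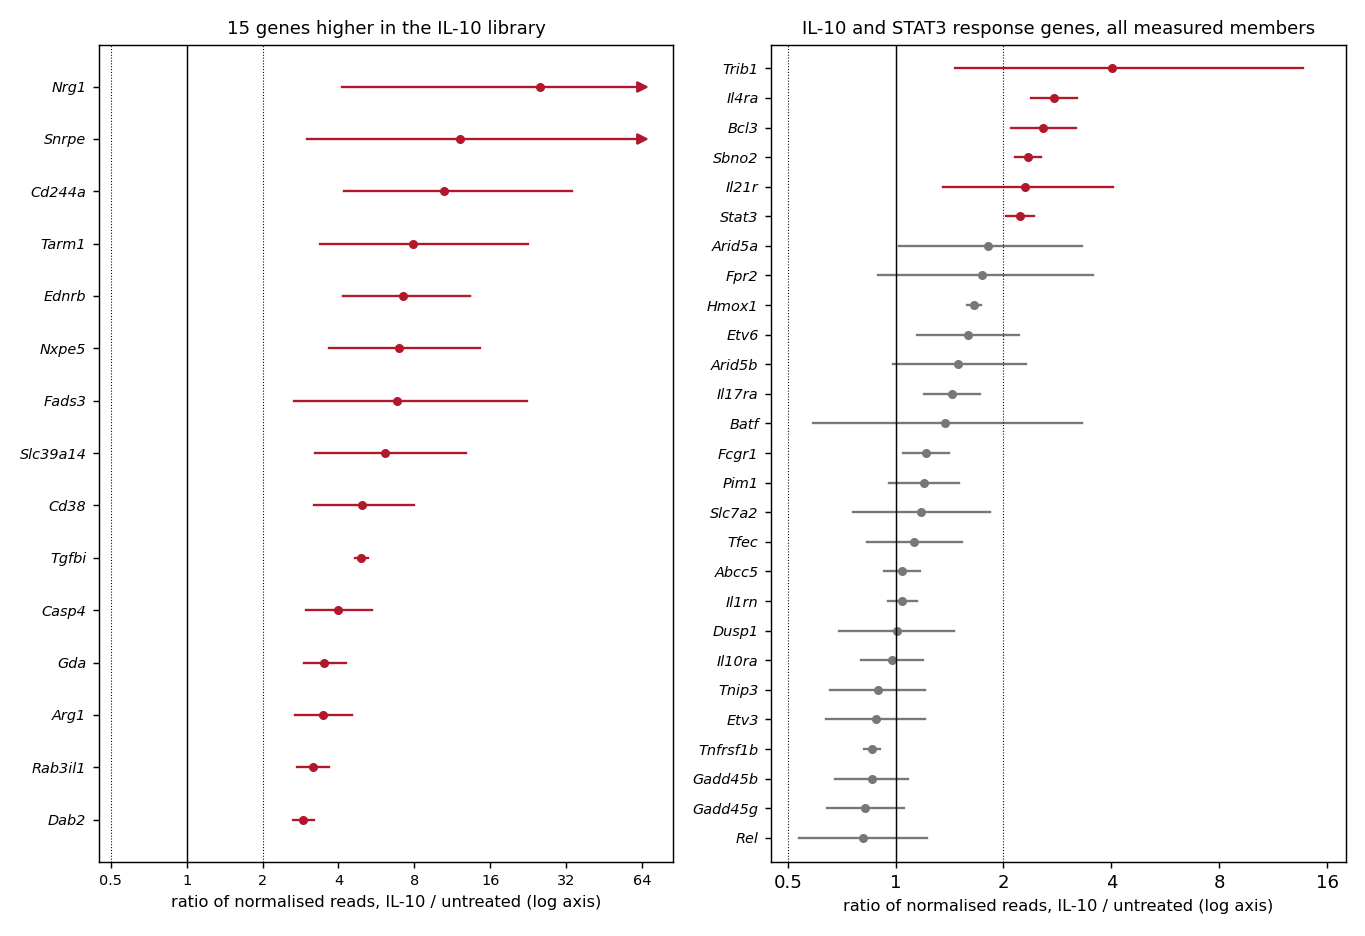
Ratio of normalised spliced reads, IL-10 library over untreated library, on a log axis, for the 15 genes highest by the lower bound of the ratio (left) and for the 27 measured IL-10 and STAT3 response genes (right). Points are ratios, lines 95% intervals of counting error and dotted lines 0.5 and 2, and 6 of the 27 response genes are red (higher), the rest are grey (neither), and arrows mark intervals that run beyond 64.

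Genes known to respond to IL-10 or Stat3 were higher as a group in the IL-10 library. Of 39 listed genes 27 were measured, 6 were at least 2-fold higher and 0 lower. These were the NF-kB regulator gene Bcl3 (2.58-fold, 95% interval 2.10 to 3.18), the IL-4 receptor gene Il4ra (2.76-fold, 2.39 to 3.21), Sbno2, a repressor of NF-kB signalling (2.34-fold, 2.15 to 2.55), Stat3 itself (2.22-fold, 2.03 to 2.43), the IL-21 receptor gene Il21r (2.30-fold, 1.35 to 4.05) and the pseudokinase gene Trib1 (20 reads against 5, 4.03-fold, 1.47 to 13.7). Bcl3, Il4ra and Sbno2 were higher on every intron with 5 or more reads, 8, 12 and 34 introns, and Stat3 on 22 of 24. The heme oxygenase gene Hmox1, with 4946 and 3004 reads, stood at 1.66 (1.58 to 1.74). Of the other genes fixed in advance, ratios were near 1 for the receptor chain genes Il10ra (0.978, 0.803 to 1.19) and Il10rb (1.10, 1.01 to 1.201) and the receptor antagonist gene Il1rn (1.04, 0.951 to 1.14). With introns shared with read-through models included, Il10rb stood at 1.03 (0.960 to 1.11). The repressor gene Etv3 had a ratio of 0.880 (0.638 to 1.21). The median log2 ratio of the list was 0.28 (0.16 to 0.52 by resampling of reads), at percentile 100 of random lists matched on abundance. With at least 100 reads per gene it was 0.12 over 20 genes, at percentile 96.0. On the intron with the most reads alone Stat3 (log2 ratio 0.57) and Trib1 (1.45) were no longer called.

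The suppressor of cytokine signalling gene Socs3 and Nfil3 have a lone matched junction each, which the naming rule leaves out, and their values were taken after the data were seen. Socs3 had 9 reads in the IL-10 library and 0 in the untreated library. Set against a floor of 3 reads in the untreated library, Socs3 was 3.02-fold higher, and the lower 95% bound by counting error was 1.99. Nfil3 had 9 and 3 (3.02-fold, 0.754 to 17.3), and with fewer than 20 reads neither gene was called. In the same way the mRNA decay factor gene Zfp36 had 96 and 58 (1.67-fold, 1.19 to 2.35) and the gene Fgl2 had 26 and 2 (13.1-fold, 3.28 to 113.8).

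Members of the JAK-STAT pathway were also higher as a group. Of 31 genes 23 were measured, Stat3 and the kinase gene Jak3 (332 against 154 reads, 2.17-fold, 1.79 to 2.65) were called higher, and 0 were lower. The inhibitor gene Pias3 (1.499, 1.01 to 2.24) and the shared receptor chain gene Il6st (1.47, 1.26 to 1.71) had intervals above 1, as did 8 members in all, while the interval of 1 member lay below 1. The median log2 ratio was 0.15 (0.04 to 0.25), at percentile 98.8. On the intron with the most reads alone it was 0.14, at percentile 86.2.

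Most inflammatory cytokine genes had few reads in both libraries, and of 30 listed genes 12 were measured, with 0 called. The tumour necrosis factor gene Tnf, also fixed in advance, had 33 reads with IL-10 and 53 without (0.627, 95% interval 0.393 to 0.987), and the interleukin gene Il1a had 55 and 100 (0.554, 0.391 to 0.777). Osm (0.576, 0.258 to 1.22) lay below 1 within its counting error, while the prostaglandin enzyme genes Ptgs1 (1.75, 1.33 to 2.30) and Ptges (1.72, 0.913 to 3.33) lay above 1. The list's median log2 ratio of -0.14 (-0.33 to 0.07) was at percentile 16.1, and it was 0.10 with at least 100 reads per gene and 0.10 on the intron with the most reads.

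Of 12 measured chemokine genes, the monocyte attractant gene Ccl7 was called higher (22 against 9 reads, 2.46-fold, 1.09 to 6.07) and 0 were lower. Its neighbour Ccl2 had 797 and 426 reads (1.88-fold, 1.67 to 2.12), Ccl4 had a ratio of 1.64 (1.11 to 2.46) and Ccl9 of 1.55 (1.35 to 1.79). Among 25 measured chemokine and cytokine receptors, the Ccl2 receptor gene Ccr2 (65 against 25 reads, 2.62-fold, 1.63 to 4.33), Il4ra and Il21r were called higher and 0 lower, and Il1r1 had a ratio of 1.84 (1.15 to 3.00). The median log2 ratios were 0.21 for the chemokines (percentile 97.0) and 0.11 for the receptors (percentile 95.04), inside the central 95% of random lists. The call of Ccl7 ended with a 99% interval and on the intron with the most reads, and the percentile of the chemokines was 50.5 on that intron and 99.8 with at least 100 reads per gene.

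Genes of alternative activation, the macrophage state induced by IL-4, included called members in the higher direction and none in the lower. Arg1 and Il4ra were called higher among 18 measured members, and the resistin-like gene Retnla had 34 reads with IL-10 and 19 without (1.80, 0.999 to 3.34), while the chitinase-like gene Chil4 had 53 and 103 (0.518, 0.365 to 0.729). The value of Chil4 is uncertain, since 2 of its 5 introns with 5 or more reads lay on the same side as the sum, and 29 of its untreated reads fell on an intron with 0 reads in the IL-10 library. The median log2 ratio of the list was 0.20 (0.04 to 0.55), at percentile 97.4. Under alternatives the percentile ranged from 96.5 to 99.98.

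Antigen presentation and interferon-stimulated genes showed no shift as groups. Of 20 measured antigen presentation genes, the class I gene H2-Q7 was called lower with 12 reads against 27 (2.23-fold lower, 1.09 to 4.84), a value that is uncertain because class I genes are near-identical copies. The costimulatory genes Cd80 (1.79, 0.745 to 4.60) and Cd40 (1.75, 0.966 to 3.26) had intervals that included 1, and the checkpoint ligand gene Cd274 stood at 1.54 (1.26 to 1.89). Of 29 measured interferon-stimulated genes 0 were called, with Oasl1 at 0.515 (0.294 to 0.881), Usp18 at 0.525 (0.310 to 0.868), Psmb9 at 0.676 (0.464 to 0.976) and Trim30a at 1.47 (1.01 to 2.15). The median log2 ratios were 0.04 (percentile 74.7) and -0.02 (percentile 45.9). Among 28 Fc, scavenger and phagocytic receptors 0 were called, but several had intervals well clear of 1: the scavenger receptor gene Msr1 had 3370 and 1867 reads (1.82, 1.72 to 1.92), the beta-glucan receptor gene Clec7a had 1101 and 1975 (0.561, 0.521 to 0.605), and the Fc receptor genes Fcgr4 and Fcgr2b stood at 1.57 (1.24 to 1.99) and 1.55 (1.42 to 1.70). That list had a median of 0.06, at percentile 90.7.

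Signalling and stress lists held single called members. In the toll-like receptor and NF-kB list of 29 measured genes only Bcl3 was called, with Ticam2 at 1.58, Tirap at 1.52 and Traf6 at 1.39, each with an interval that included 1, and a list median of -0.02 (percentile 34.1). Among 21 immediate early and stress genes the AP-1 gene Fosl2 was higher (60 against 29 reads, 2.08-fold, 1.32 to 3.37), Csrnp1 had 22 and 11 reads (2.01, 0.936 to 4.60), and Dnajb1 (0.701) and Ddit3 (0.717) had intervals that included 1. The median was -0.04 (percentile 37.9). Counting every junction within the gene, Fosl2 had a log2 ratio of 0.93 and was no longer called.

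Mitochondrial respiratory chain genes were slightly lower as a group in the IL-10 library. Of 29 measured members 0 were 2-fold different, 13 had an interval below 1 and 2 an interval above 1. The complex I gene Ndufb10 had a ratio of 0.732 (0.646 to 0.830) and the complex II gene Sdhc of 0.772 (0.642 to 0.927), against 1.65 (1.13 to 2.42) for Ndufa1 and 1.42 (1.13 to 1.77) for Sdhd. The value of Sdhc is uncertain, since 2 of its 5 introns with 5 or more reads lay on the same side as the sum. The median log2 ratio of the list was -0.12 (-0.18 to -0.08), at percentile 0.880 of random lists. Genes often used as references were likewise lower: of 10 measured, Eef2 stood at 0.784 (0.758 to 0.812), Hprt at 0.834 (0.758 to 0.917) and Actb at 1.16 (1.14 to 1.19), with a median of -0.18 (-0.24 to -0.08) at percentile 1.87. On the intron with the most reads they were -0.07 (percentile 9.68) and -0.04 (percentile 29.6), and after removal of the trend with transcript length and GC content -0.06 (percentile 5.10) and -0.12 (percentile 5.62). The values of Eef2 and Actb are uncertain, since 6 of 13 and 3 of 5 of their introns match a processed pseudogene.

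Other metabolic and housekeeping lists had medians inside the central 95% of random lists, though glycolysis and ribosomal proteins left it under alternatives. Of 17 measured genes of iron, heme and metal handling Slc39a14 was higher, with Mt2 at 1.45 (1.15 to 1.82) and Slc40a1 at 0.697 (0.263 to 1.76). Among 20 oxidative stress genes the glutathione peroxidase gene Gpx4 was called (31 against 13 reads, 2.40-fold, 1.22 to 5.0), a value that is uncertain because all 6 of its introns match a processed pseudogene, while Sod2 stood at 1.49 (1.36 to 1.64) and Srxn1 at 0.687 (0.503 to 0.934). Glycolysis and glucose uptake had 19 measured genes and 0 calls, with the glucose transporter gene Slc2a6 at 0.566 (0.418 to 0.762), the glycolytic regulator gene Pfkfb3 at 1.69 (1.44 to 1.98), Slc16a3 at 0.623 and Pfkm at 0.663. Cholesterol efflux and lipid handling (26 genes) and cholesterol synthesis (19 genes) had 0 calls, with Pparg at 0.659 (0.551 to 0.786), Ppard at 1.63 (1.09 to 2.46), Scd1 at 1.64, Cyp27a1 at 0.632, Sc5d at 0.671 (0.532 to 0.846), Fdft1 at 1.47 and Stard4 at 0.705. Among 34 lysosome and autophagy genes, 0 were called and Atg12 (0.749), Tfeb (0.753), Sqstm1 (0.801) and Grn (1.25) differed most. The 20 measured mRNA decay factors (Dcp1a 1.48, Dcp2 1.44, Tia1 0.710, Hnrnpd 1.38), the 33 splicing factors (Srsf10 0.441, U2af2 1.505, U2af1 1.47, Hnrnpk 1.41) and the 21 cell cycle genes (Aurka 0.424, Plk1 1.89, Cdk6 1.64, Mcm2 1.45) held 0 calls. Of 42 cytosolic ribosomal protein genes 14 were measured, Rps4x was called on 22 against 10 reads (2.21-fold, 1.01 to 5.24), uncertain because 5 of its 6 introns match a processed pseudogene, and Rps14 (1.85, 1.67 to 2.04) and Rpl38 (0.687, 0.455 to 1.03) were not. The call of Rps4x ended under the median-of-ratios scaling. Processed pseudogenes also match introns of Srsf10 (3 of 6), U2af2 (8 of 11), U2af1 (5 of 7) and Hnrnpk (11 of 14). The same holds for Rps14 (3 of 5), Rpl38 (2 of 4), Fdft1 (3 of 9) and Plk1 (2 of 9), so these values are uncertain too. Percentiles of these medians were 23.8 for metal handling, 33.3 for oxidative stress, 67.4 for glycolysis, 72.4 and 19.8 for the lipid lists, 47.6 for lysosome and autophagy, 94.1 for decay factors, 46.5 for splicing factors, 3.64 for cell cycle and 87.7 for ribosomal proteins. On the intron with the most reads the percentiles were 99.7 for glycolysis (median 0.31) and 98.2 for ribosomal proteins (0.26), and the latter were at 98.5 with read-through introns and single-junction genes and at 97.6 with the length and GC trend removed.

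**Figure D2:**
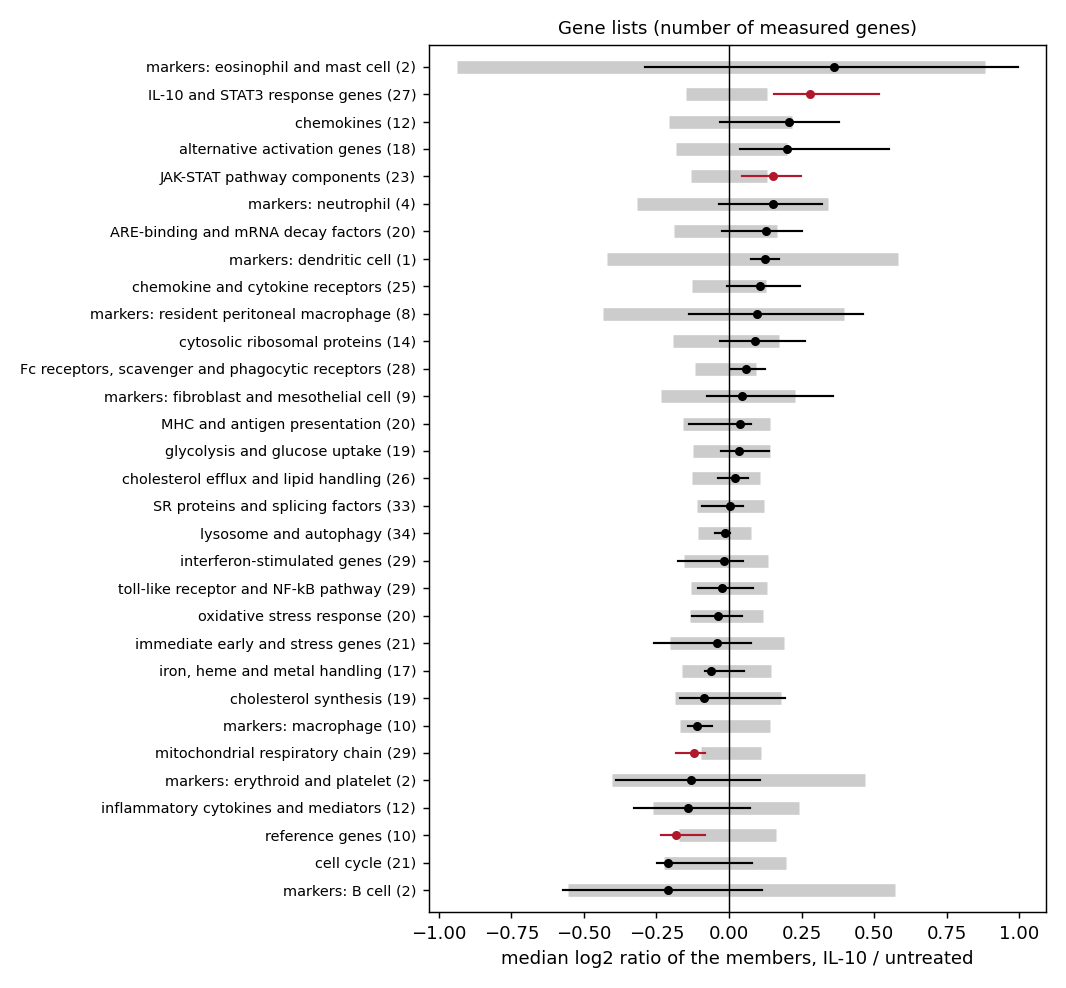
Median log2 ratio (IL-10 library over untreated library) of the measured members of 31 gene lists, with lines for their 95% range when reads are resampled and grey bars for the central 95% of 10000 random lists. The lists outside their grey bars, in red, are the IL-10 and STAT3 response genes (0.28) and JAK-STAT components (0.15) on the higher side, and the respiratory chain (-0.12) and reference genes (-0.18) on the lower side.

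Over the 31 lists with measured members, 2 had a median above the central 95% of random lists and 2 below it, where 1.55 lists outside would be expected by chance if lists were independent.

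Few junctions passed the thresholds for a difference in share. Shares of junctions were compared at 8548 donor or acceptor sites with at least 20 reads in each library, holding 17436 junctions, and 27 junctions at 18 sites, among them sites in 16 named genes, differed by at least 20 percentage points with intervals that did not overlap. Of these, 20 matched an annotated intron and 7 did not. The secretory coat gene Sec31a differed most: at an acceptor on chromosome 5 (mm9), the intron from 100815223 to 100817552 took 20 of 26 reads (76.9%, 95% interval 56.4 to 91.0) with IL-10 and 7 of 25 (28%, 12.1 to 49.4) without, and the longer intron from 100815223 to 100819777 took the rest. In Naip2, an inflammasome sensor gene, the intron on chromosome 13 from 100922602 to 100924809 took all 21 reads with IL-10 and 14 of 27 (51.9%) without. In Chil4 on chromosome 3, an unannotated intron from 106017938 to 106019320 took all 36 reads with IL-10 and 34 of 63 (54.0%) without, where the annotated intron to 106022357 took 0 and 29 reads. In the deubiquitinase gene Usp15 on chromosome 10, the intron from 122583995 to 122590096 took 38.5% (20.2 to 59.4) and 82.0% (66.5 to 92.5), and the longer intron to 122600648 took 57.7% and 17.9%. The elongation factor gene Eef1d (75.0% against 34.9%) and the splicing regulator genes Mbnl2 (11.1% against 50% for its shorter intron) and Rbm39 followed, and 1 of the 10 largest differences, on chromosome 10 from 79174045 to 79174242, had no gene name (44.8% against 2.5%). The shorter aligned side of that unnamed junction was 9 bases in each library. In Rbm39 the annotated intron from 155993487 to 155998563 on chromosome 2 took 61.3% (48.1 to 73.4) of 62 reads with IL-10 and 100% (93.5 to 100) of 55 without. An unannotated intron from 155996215 to 155998563 took 22 and 0 reads, with 21 bases on its shorter aligned side. A part of the aligner in these differences was not tested. The deepest of the 18 sites was in the vesicle scission gene Dnm2, singled out after its values were seen, where the intron on chromosome 9 from 21304814 to 21307985 took 95 of 180 reads (52.8%, 45.2 to 60.3) with IL-10 and 83 of 327 (25.4%, 20.7 to 30.5) without. With at least 50 reads per library at a site the count was 5 junctions. In counts simulated without any difference and with counting error alone, 8 of 20246 comparisons of a junction's share were called. A junction could enter these comparisons at both its donor and its acceptor. The 8 stand against the 27 junctions called in the real libraries, so counting error alone could account for some of the 27. Spread beyond counting error was not simulated.

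Reads on junctions that matched no annotated intron made up 1.90% (95% interval 1.88 to 1.91) of junction reads in the IL-10 library and 2.01% (1.999 to 2.03) in the untreated library. They lay on 15165 of 109870 junctions (13.8%) and 15489 of 110102 (14.1%). A pair of junctions on chromosome 17 between 35403672 and 35580308 held 1764 of the 81218 such untreated reads each, and 0 reads with IL-10. Most of the difference in share rests on this pair, which also counts among the junctions with at least 10 reads. Among junctions with at least 10 reads the shares of reads were 1.31% and 1.42%.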

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

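All 5 results below are junctions without a gene name that carried more reads in the IL-10 library than in the untreated library, in junctions that the gene comparison leaves out. Junctions of this kind also occurred in the untreated library alone: on chromosome 17 from 35403672 to 35482788 and from 35482804 to 35580308 (0 against 1764 reads each), on chromosome 2 from 13501146 to 13501647 (0 against 193) and on chromosome 10 from 79867035 to 79869443 (0 against 143). The tests on the paired junctions were chosen only after the result was seen.

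On chromosome 6, within Gpnmb, the junctions from 48998101 to 48999256 and from 48999257 to 49000408 had 529 and 531 reads in the IL-10 library and 0 in the untreated library. Both lie inside a longer intron with 27341 and 27686 reads. These may be an intron split in 2 by the aligner, because 0 bases of exon lie between the 2 introns of this pair and of a similar pair in Cd36, and the longer intron is itself a junction. With 0 bases between its introns, an exon between them used in the IL-10 library only is ruled out for the Gpnmb pair. A further junction inside the longer intron, from 48999352 to 49000408, had 153 reads with IL-10 and 145 without. An exon between it and the first junction of the pair was not tested.

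The Cd36 pair had its reads (189 and 197) in the untreated library, against 0 and 2 with IL-10. A pair on chromosome 10 from 116715778 to 116728084, also with 0 bases between, had 31 reads on each junction with IL-10 and 23 without. Against the split stands a pair on chromosome 10 from 80825773 to 80826297, with 0 bases between. It had 27 reads on each junction with IL-10 and 0 without, its joined intron was not a junction, and it stays unexplained. The pair on chromosome 17 has 15 bases between, and its exact joined intron was not a junction either. Its introns, of 79117 and 97505 bases, together have the length of a junction on the opposite strand with the same start. That junction, from 35403672 to 35580293 (176622 bases), had 2766 reads with IL-10 and 1810 without. A split of that intron was not tested, so the chromosome 17 pair is not counted for or against the split. Why reads of a pair fell in a single library was not tested.

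On chromosome 10, the junction from 127929830 to 127930071 had 237 reads with IL-10 and 119 without (2.01-fold, 1.60 to 2.52). On chromosome 14, the junction from 26694271 to 26975530 had 95 and 45 reads (2.13-fold, 1.48 to 3.10). On chromosome 5, the junction from 33085124 to 33088831 had 84 and 42 (2.01-fold, 1.38 to 2.99). No cause was tested for these 3 junctions.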

How the results depend on the processing

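The alternatives were fixed before the data were examined, except that read-through introns with single-junction genes and the removal of the length and GC trend were chosen only after the result was seen. No paired analysis was possible because each group held 1 library, and no setting can replace replication. All 44 called genes among those named kept their direction in 6 settings; their calls were kept for 44 with TMM, 43 with the median of ratios, 42 with the gene span, 41 with a 99% interval and 24 with the most-read intron alone. Over all genes, the most-read intron alone called 175 higher and 104 lower, of which 45 and 19 were among the 142 and 123. The IL-10 and STAT3 list stayed between percentiles 96.0 and 100, and the respiratory chain between 0.80 and 9.68. The cause of the differences below was not tested, except that a stricter or looser threshold changes a count by construction.

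Against 142 higher and 123 lower genes, 198 were higher and 187 lower with no minimum of reads, 37 higher and 10 lower with 100 reads, 350 and 333 at 1.5-fold, 52 and 28 at 3-fold, and 106 higher and 76 lower with a 99% interval. With 100 reads, list medians were 0.1168 for IL-10 and STAT3 response and 0.0977 for inflammatory cytokines. With no minimum the dendritic cell median was 2.1256. With the most-read intron alone, medians were 0.1036 for inflammatory cytokines, 0.0978 for antigen presentation, 0.309 for glycolysis, 0.0502 for lysosome, 0.3191 for mRNA decay factors, -0.0663 for the respiratory chain, -0.038 for reference genes, -0.0543 for macrophage markers, 1.2691 for eosinophil and mast cell markers and 0.4415 for dendritic cell markers. With read-through introns and single-junction genes the macrophage median was -0.049. With the length and GC trend removed, antigen presentation was 0.1203 and the respiratory chain -0.0636.

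Against 27 junctions whose share differed, 5 did with 50 reads, 47 with 10 reads, 43 with 10 points and 14 with annotated junctions only. Reads outside the annotation were 1.681% (IL-10) and 1.791% (untreated) among junctions with at least 2 reads, and 1.309% and 1.424% with at least 10.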

Other observations

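Further genes with 100 reads or more differed between the libraries, and those named here were chosen after their values were seen. Higher in the IL-10 library were the platelet and leukocyte signalling gene Plek (1990 against 886 reads, 2.26-fold, 95% interval 2.09 to 2.45), the class I transactivator gene Nlrc5 (143 against 39, 3.69-fold, 2.58 to 5.41) and the nucleoside transporter gene Slc28a2 (626 against 206, 3.06-fold, 2.61 to 3.60). The membrane protein gene Ms4a6d (2.05-fold, 1.86 to 2.26) and the motor gene Kif3a (2.02-fold, 1.80 to 2.26) were also higher. The receptor kinase gene Grk5 had 30 reads with IL-10 and 71 without (2.35-fold lower, 1.51 to 3.73), and the caveolin gene Cav2 had 47 and 105 (2.22-fold lower, 1.56 to 3.20).

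Splice shares beyond the 10 largest also differed. In Ptprc, which encodes CD45, the intron on chromosome 1 from 140012220 to 140022879 took 20 of 67 reads (29.9%, 19.3 to 42.3) with IL-10 and 0 of 44 without. The shorter aligned side of that junction was 24 bases, against 68 for the other called junction at its donor. A part of the aligner in this difference was not tested. In Immt, a gene of mitochondrial cristae, the intron on chromosome 6 from 71801875 to 71802759 took 10 of 45 reads (22.2%) and 1 of 55 (1.82%). Both genes were chosen after their values were seen.

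In the weighing of 2 patterns below, the tests on length and GC content, scaling, the most-read intron, pseudogenes and the naming of junctions were chosen only after the result was seen. For length and GC content and for pseudogenes, the outcome each explanation needs was written down before the test was run.

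Respiratory chain genes were slightly lower in the IL-10 library. A bias by transcript length or GC content could account for part of this, since removal of that trend moved the list median to percentile 5.10. Library scaling is argued against by construction, because a factor for a library moves all genes alike, and the list median was at percentile 0.880 of random lists from the same libraries. That percentile is the value that first singled out the list, so it is no separate test. The most-read intron alone gave -0.0663, and its difference from the median over all introns in 28 genes was 0.06 (-0.03 to 0.13), so a part played by that intron is neither shown nor excluded. An effect of IL-10 itself was not tested and stays open.

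Few spliced reads fell on ribosomal protein genes, and 28 of 42 were not measured. Reads aligned to processed pseudogenes were neither shown nor excluded as the source. In 6 ribosomal protein genes the median log2 ratio of introns that match a pseudogene over the others was -4.364 (-6.29 to -0.84), but these were measured genes kept for reads on their other introns, which lowers the ratio, and none of the 28 was among them. Over all 419 genes kept by the same rule it was -1.20 (-1.53 to -0.92). For 1 intron without a match against the others, in 391 of these genes, it was 0.17 (-0.16 to 0.31). Those introns were themselves part of the rule, so they do not measure its effect. Genes missed by the naming of junctions are not most of the 28: junctions outside every gene value, with the exact length of an intron of the gene, held 20 or more reads for 7 of the 28 (25%, 10.7 to 44.9). In the unmeasured genes 99 of 134 introns (73.9%) matched a pseudogene, but 27 of the 35 others had 0 reads as well, so the part of pseudogenes stays open.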
